A study of Homo sapiens with 6 samples.

How the data were processed

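RNA sequencing was performed on 6 libraries of T24 cells, 3 labelled sgNC and 3 labelled sgOTUD1, prepared from total RNA with an NEBNext Ultra RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. A table of 58735 genes was used, with 1 column per library. Its deposited values are FPKM, per the file headers. The submitters' processing notes name featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build hg38. The aligner and the strand setting are not given in the sources used here.

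All 58735 gene identifiers were in GENCODE 29 and 58708 symbols were equal to it. Exon length is that of the union of all exons annotated for a gene. Multiplied by the exon length of the gene in that annotation, the deposited FPKM values were whole multiples of 1 number per library for 100% of values (tolerance 0.001 reads), which recovered the read numbers. These 6 numbers equal the geometric mean of the library totals times median-of-ratios size factors, so the deposited FPKM values already carry a scaling between libraries. Recovered reads ranged from 16697370 to 17191933 per library. Replicate pairs differed beyond sampling noise, with a chi-square per gene of 2.07 to 3.86 within groups against 64.1 to 75.8 between groups, so no library was counted as a repeat of another. Values were at 0 in all libraries for 28313 genes.

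The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust options) on log2(FPKM + 1), two-sided, with group as the only term and Benjamini-Hochberg adjustment. Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, 14658 in all, of which 11385 are protein-coding. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Files turned out to hold FPKM alone, so no count test was the main test. OTUD1 was also given an exact permutation test of its 6 values. Gene lists with at least 5 tested members were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry. Tables were read with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.

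The test design, 31 gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule named OTUD1, then the 10 largest increases and 10 largest decreases among protein-coding genes past an adjusted p of 0.05, with a mean FPKM of at least 1 in a group and no overlap between groups. It also named, per list, up to 2 members that rose and 2 that fell with the smallest adjusted p. Some of these genes and 1 list past camera are not reported here. Alternatives set at that time were a replicate block, leaving out each replicate, no filter, a mean FPKM of at least 5, median-ratio rescaling, TPM, limma without trend and robust options, an offset of 0.1, and stricter thresholds.

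4 alternatives were chosen after seeing the data. The first length correction fitted a natural spline of log2 exon length (4 degrees of freedom) per library to the deviations of nuclear protein-coding genes and subtracted it, and a variant added transcript GC content. The second length correction was written after the results and the simulation of the first had been seen. It estimated the spline on genes of mean FPKM of at least 5 and divided it out of FPKM before the offset was added. Values called length-corrected come from the first, and both are reported. The last was limma-voom on the recovered reads.

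The fits were tested on simulated reads for the 14658 genes of the comparison of sgOTUD1 with sgNC, with 50 genes changed at each fold. Without a length trend, 34% of genes changed 1.25-fold, 86% changed 1.5-fold, 92% changed 2-fold and 96% changed 4-fold were called in the right direction, and 3.75% of the calls were false. With a simulated trend of -0.15 per doubling of length, 93.9% of the calls were false without correction, 22.1% with the first length correction and 20.1% with the second. Neither correction removes such a trend fully, and length-corrected calls of single genes carry an error of unknown share. A false share depends on how many genes change. The 22.1% is of 213 calls, whereas the same correction called 3820 genes higher and 4120 lower in the data. The simulated shares therefore do not carry over to the data.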

Results

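Gene expression was measured by RNA sequencing of total RNA from cells labelled T24, a human bladder cancer line. The series title gives the comparison as control against OTUD1 knockout cells, and the design text names 3 replicates of each. Control libraries are labelled sgNC and carry an empty vector. The other libraries are labelled sgOTUD1. OTUD1 encodes a deubiquitinase of the OTU family, an enzyme that removes ubiquitin from proteins. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Between 16697370 and 17191933 reads per library were assigned to genes.

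OTUD1 itself was not lower in the libraries labelled sgOTUD1. The gene (ENSG00000165312) lies on chromosome 10 from 23439458 to 23442390 on the plus strand of hg38, and its annotation is 1 exon of 2933 nt. It was at 14.7 ± 0.83 FPKM in sgNC (SD, n = 3) and 17.05 ± 0.83 FPKM in the libraries labelled sgOTUD1 (SD, n = 3), from a mean of 764 and 820 reads. The log2 fold change was 0.20 (SE 0.054), with a limma adjusted p of 0.0167 and a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. This direction goes against the label, although a small insertion or deletion at a guide's cut site need not lower the transcript, and the level therefore does not check a knockout of that kind. The limma call ended without sgNC replicate 1 (log2 fold change 0.17, adjusted p = 0.0565), without sgOTUD1 replicate 2 (0.17, adjusted p = 0.0555), and with median-ratio rescaling (0.07) or TPM (0.06). Removing the relation of fold change to gene length left a log2 fold change of 0.02 for OTUD1 (limma adjusted p = 0.715), and a second way of removing it gave -0.06.

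**Figure D1:**
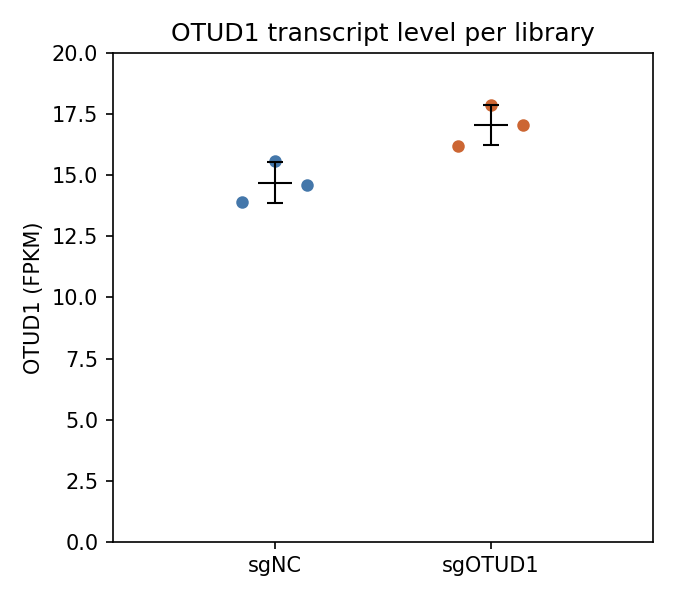
OTUD1 level in FPKM (vertical axis) in each sgNC library and each library labelled sgOTUD1, as points, with the group mean and SD in black. The 3 libraries labelled sgOTUD1 lie between 16.2 and 17.9 FPKM, and the 3 sgNC libraries between 13.9 and 15.6 FPKM.

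The comparison of the groups asks which transcripts differ between control cells and cells labelled as OTUD1 knockout. Heat shock genes led the increases in the libraries labelled sgOTUD1. HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946, plus strand), which encodes an inducible cytosolic HSP70 chaperone, rose from 33.9 ± 4.2 to 320.2 ± 19 FPKM, a log2 fold change of 3.21 (SE 0.089, limma adjusted p = 2.42e-06). Its near-identical neighbour HSPA1B rose from 24.7 to 207 FPKM, and the division of reads between these 2 genes is uncertain. HSPA6 rose from 1.51 to 18.7 FPKM and the HSP40 co-chaperone DNAJB1 from 44.6 to 195 FPKM. DDIT3, a transcription factor of endoplasmic reticulum (ER) stress also called CHOP, rose from 13.6 to 85.8 FPKM. The other large increases were GADD45B (21.9 to 102 FPKM), ANKRD37 (1.92 to 11.9 FPKM), the EGF receptor ligand HBEGF (6.90 to 33.3 FPKM), ID2 (0.800 to 6.77 FPKM) and PHLDA2 (13.5 to 60.7 FPKM).

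The largest decreases included 3 mitochondrially encoded transcripts, MT-ATP8 (84.1 to 16.2 FPKM), MT-ND6 (1168 to 295 FPKM) and MT-ND5 (1088 to 281 FPKM). MT-ATP8 overlaps MT-ATP6, and MT-ND6 abuts MT-ND5 on the opposite strand. The strand setting of the counting is not given in the sources used here. SLFN5 (ENSG00000166750, chromosome 17, 35243036 to 35273655, plus strand) fell from 15.3 ± 0.43 to 2.68 ± 0.18 FPKM, a log2 fold change of -2.15 (SE 0.052, limma adjusted p = 1.47e-06). HPS6 fell from 13.1 to 2.75 FPKM, MGAM from 5.01 to 0.834 FPKM, ZNF629 from 4.84 to 0.948 FPKM, ZC3H4 from 5.49 to 1.204 FPKM, AHNAK2 from 25.6 to 8.03 FPKM and PPP1R10 from 3.92 to 0.744 FPKM.

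Over the 14658 genes tested, 4577 were higher and 3615 lower in the libraries labelled sgOTUD1 at a limma adjusted p under 0.05, and 294 of the higher and 127 of the lower also changed by more than 2-fold. Values of the groups did not overlap for 64.0% of the genes, against 10% by chance. The split between directions depends on scaling. With the deposited scaling 55.9% of the called genes were higher, against 39.6% with median-ratio rescaling on genes of higher level and 36.8% with TPM. The filter was applied after rescaling, so TPM tested 19388 genes and median-ratio rescaling 14670. The TPM share thus reflects a larger set of genes as well as the scaling. It also depends on the filter, with 66.3% higher among genes of mean FPKM of at least 5. TPM moved the median log2 fold change of the genes in common from 0.03 to -0.10.

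**Figure D2:**
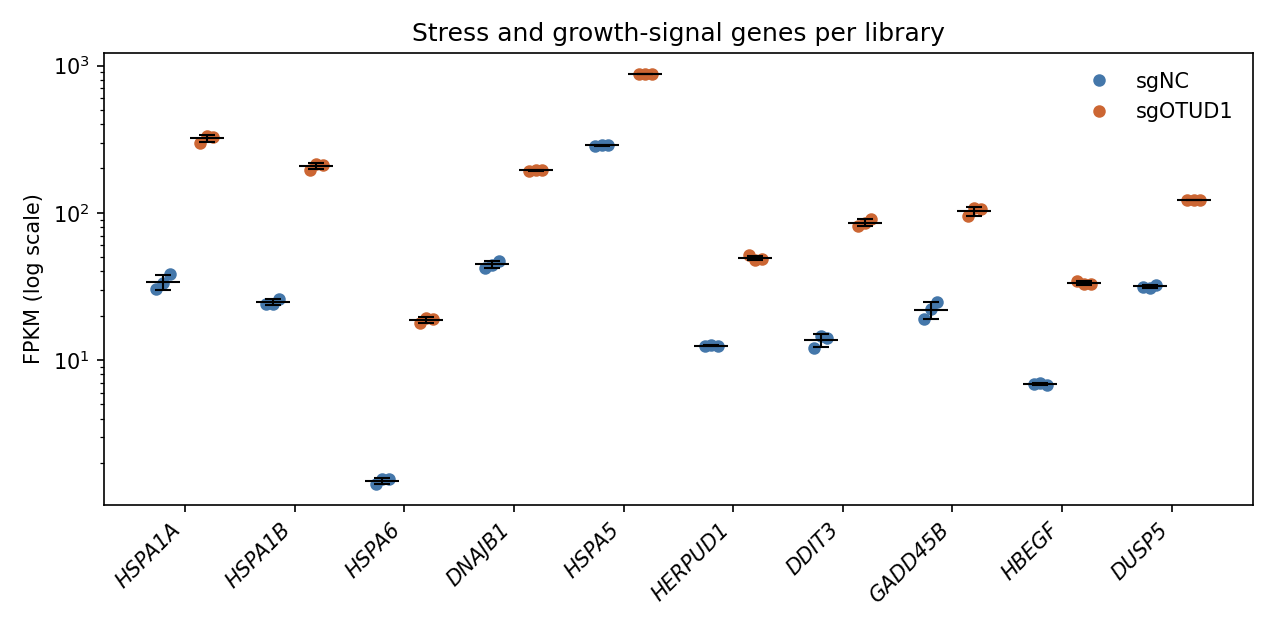
Levels of 10 genes in FPKM (vertical axis, log scale) in each library, as points, with the mean and SD of each group in black; the genes were picked from those named in the text. HSPA1A rose from 33.9 to 320.2 FPKM and HSPA5 from 287 to 881 FPKM, and for all 10 genes the 3 libraries labelled sgOTUD1 lie above the 3 sgNC libraries.

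Of 31 gene lists fixed before the data were examined, 28 had at least 5 tested members. With camera at a preset inter-gene correlation of 0.01, 11 lists were higher and 2 lower in the libraries labelled sgOTUD1, in the same direction under both rescalings. None passed with an estimated correlation, where 9 lists had an unadjusted p under 0.05, and fry called 24 lists. After length correction, a setting added after the data were seen, 2 lists passed with an estimated correlation, heat shock genes and NRF2 targets (adjusted p = 0.0442 for each). The list of mitochondrially encoded genes had been fixed as a sign of RNA quality, and its fall (median log2 fold change -1.26) goes with the groups beside every list change given here.

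Heat shock genes rose together, 16 of 18 higher and 0 lower, with a median log2 fold change of 1.00 (camera adjusted p = 5.73e-09, adjusted p = 0.0909 with an estimated correlation). The constitutive HSP70 gene HSPA8 (36.4 to 113 FPKM), the small heat shock gene HSPB1 (505 to 1088 FPKM) and the mitochondrial chaperonin genes HSPD1 and HSPE1 were among them, named here after their values were seen. Of 23 unfolded protein response genes, 18 were higher and 3 lower, with a median of 0.46 (camera adjusted p = 1.39e-05, adjusted p = 0.0909 with an estimated correlation). The ER chaperone HSPA5, also called BiP, rose from 287 ± 1.2 to 881 ± 1.9 FPKM, and HERPUD1, which acts in ER-associated degradation, from 12.5 to 49.3 FPKM. SEL1L (19.4 to 15.7 FPKM) and EDEM1 (9.26 to 7.71 FPKM), of the same degradation pathway, fell. The call of SEL1L ended with length correction, where its log2 fold change went from -0.29 to -0.16 (limma adjusted p = 0.0543), and with the second length correction (-0.16, limma adjusted p = 0.0556). Integrated stress response genes, targets of ATF4, were higher in 20 and lower in 7 of 31 members (camera adjusted p = 0.00851, adjusted p = 0.148 with an estimated correlation). ATF3 rose from 10.3 to 24.5 FPKM, whereas the cationic amino acid transporter SLC7A1 (20.6 to 13.6 FPKM) and CHAC1 (7.68 to 3.92 FPKM) fell. Adjusted over the list alone, the first 2 lists had the same counts, and 22 ATF4 targets were higher and 7 lower. The call of the ATF4 list ended among genes of mean FPKM of at least 5 (camera adjusted p = 0.172), where its median was 0.25 against 0.23 in the main test.

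Targets of NRF2, the transcription factor of the antioxidant response, were higher in 17 and lower in 1 of 19 members, with a median of 0.69 (camera adjusted p = 1.21e-07, adjusted p = 0.0909 with an estimated correlation). The thioredoxin reductase TXNRD1 rose from 34.7 to 79.0 FPKM and OSGIN1 from 5.48 to 15.8 FPKM. SLC7A11, the cystine transporter, was the exception at 9.31 against 7.99 FPKM, and its call ended without sgNC replicate 1 (limma adjusted p = 0.0615), without sgNC replicate 2 (0.0599) and without sgOTUD1 replicate 2 (0.0561). Its log2 fold change went from -0.20 to -0.07 with length correction (limma adjusted p = 0.279) and to -0.08 with the second length correction (limma adjusted p = 0.255), so it was not called there. Hypoxia and glycolysis genes were higher in 27 and lower in 2 of 33 members, with a median of 0.35 (camera adjusted p = 1.39e-05, adjusted p = 0.148 with an estimated correlation). ANKRD37 and the peptide hormone ADM (43.8 to 141 FPKM) rose, and the phosphofructokinase PFKP (45.3 to 36.2 FPKM) and the oxygen sensor EGLN1 (7.52 to 6.18 FPKM) fell. Adjusted over the list alone, 3 hypoxia genes were lower, and the NRF2 counts were the same.

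Of 33 nuclear genes of oxidative phosphorylation, 30 were higher and 0 lower, with a median of 0.45 (camera adjusted p = 1.21e-07, adjusted p = 0.148 with an estimated correlation). COX5A rose from 45.7 to 71.5 FPKM and NDUFA4 from 14.6 to 24.7 FPKM. All 13 mRNAs encoded by the mitochondrial genome, the list fixed as a sign of RNA quality, were lower, with a median of -1.26 (camera adjusted p = 5.73e-09, adjusted p = 0.148 with an estimated correlation). MT-ND3, at positions 10059 to 10404 of the mitochondrial genome, fell from 1926 ± 7.5 to 802 ± 25 FPKM. Reads on mitochondrial genes made up 4.01% ± 0.18 of assigned reads in sgNC and 2.15% ± 0.08 in the libraries labelled sgOTUD1 (SD, n = 3 each). Cytosolic ribosomal protein genes were higher in 50 and lower in 0 of 51 members, with a median of 0.69 (camera adjusted p = 1.47e-15, adjusted p = 0.31 with an estimated correlation). RPL23 rose from 73.0 to 148 FPKM and RPL14 from 40.9 to 73.3 FPKM. Ribosomal protein genes have many processed pseudogenes that can take a share of their reads. Counts adjusted over the list alone were the same for these 3 lists.

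**Figure D3:**
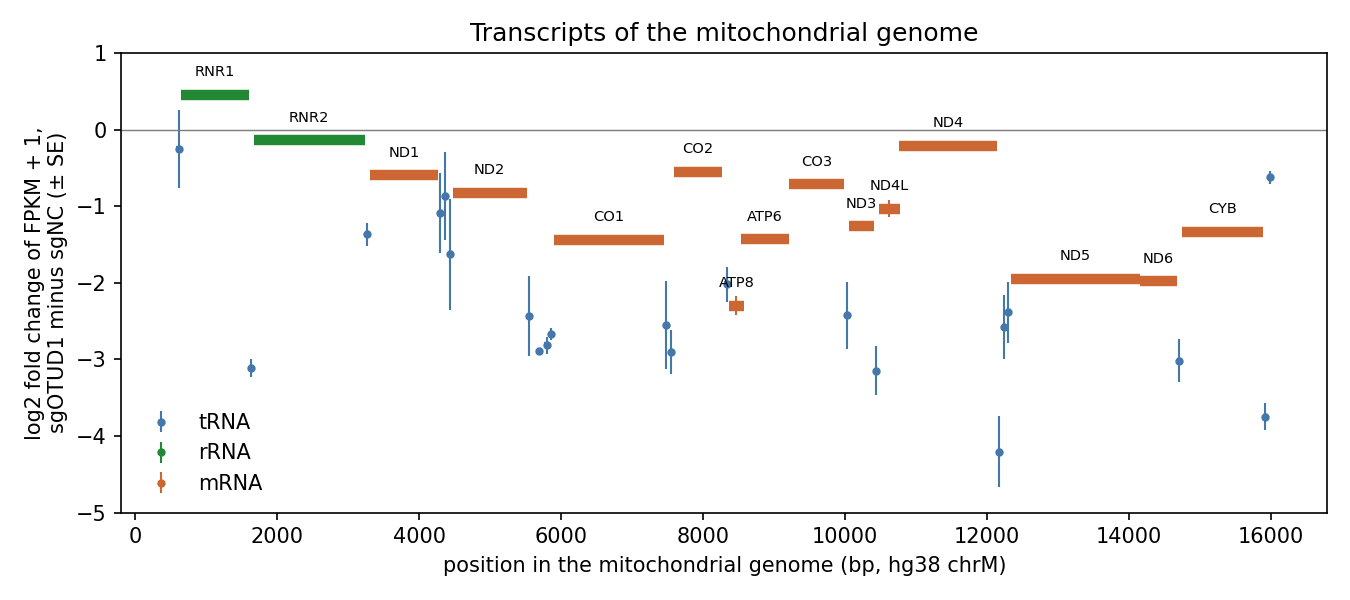
Log2 fold change on the FPKM + 1 scale (vertical axis, sgOTUD1 minus sgNC, bars are SE) of each tested mitochondrial gene at its position in the mitochondrial genome in bp (horizontal axis), with mRNAs in orange, rRNAs in green and tRNAs in blue; MT-TA, listed at 0 in all libraries labelled sgOTUD1, is left out. All 13 mRNAs lie below 0, from -2.30 for MT-ATP8 to -0.21 for MT-ND4, and the rRNA gene MT-RNR1 lies at 0.46.

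Output genes of ERK signalling were higher in 15 and lower in 5 of 22 members (camera adjusted p = 0.00565, adjusted p = 0.148 with an estimated correlation). HBEGF and the phosphatase DUSP5 (31.6 to 122 FPKM) rose, and the pathway inhibitors SPRED2 (7.09 to 4.60 FPKM) and SPRED1 (3.05 to 2.10 FPKM) fell. Targets of NF-kB were higher in 14 and lower in 3 of 26 members (camera adjusted p = 0.00949, adjusted p = 0.148 with an estimated correlation). The inhibitors NFKBIA (97.2 to 172 FPKM) and NFKBIE (13.5 to 23.6 FPKM) rose, and the adhesion gene ICAM1 (21.9 to 18.4 FPKM) and NFKB1 (11.4 to 9.69 FPKM) fell. The NF-kB call ended after length correction, where the list median fell from 0.30 to 0.12 (camera adjusted p = 0.0884), and among genes of mean FPKM of at least 5 (camera adjusted p = 0.236). Genes of MHC class I antigen presentation were higher in 13 and lower in 0 of 16 members, with a median of 0.43 (camera adjusted p = 0.000224, adjusted p = 0.205 with an estimated correlation). B2M, the light chain of the complex, rose from 86.2 to 182 FPKM and HLA-B from 145 to 266 FPKM, and reads of the similar HLA genes are uncertain. G2/M genes were lower in 21 and higher in 8 of 34 members, with a median of -0.28 (camera adjusted p = 0.00187, adjusted p = 0.304 with an estimated correlation). The proliferation marker MKI67 (43.0 to 23.5 FPKM) and the spindle gene HMMR (13.96 to 6.93 FPKM) fell, and UBE2C (177 to 241 FPKM) and PTTG1 (33.4 to 47.3 FPKM) rose. UBE2C was at -0.01 with the second length correction. Adjusted over the list alone, 16 ERK genes were higher and 22 G2/M genes lower, and the other counts were the same.

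The other 15 tested lists did not pass camera, with adjusted p from 0.129 to 0.934. Without a filter on low values 5 of them passed, TGF-beta response (camera adjusted p = 0.0339), iron handling (0.0105), G1/S (0.0157), cholesterol synthesis (0.00956) and apoptosis genes (0.0339), and iron handling genes also passed with limma-voom (0.0394). Targets of YAP/TAZ, the effectors of Hippo signalling, were split, with 6 higher and 10 lower of 21. GADD45A (115 to 243 FPKM) and NUAK2 (16.02 to 37.4 FPKM) rose, and ARHGEF17 (13.4 to 5.92 FPKM) and PTPN14 (9.22 to 5.33 FPKM) fell. Of 21 TGF-beta response genes, 13 were higher, including BHLHE40 (69.4 to 107 FPKM), and 8 lower, including LTBP2 (14.5 to 7.91 FPKM). Mesenchymal genes were higher in 6 and lower in 6 of 15. The repressor SNAI1 (2.28 to 11.6 FPKM) and vimentin, VIM (33.7 to 48.2 FPKM), rose, and the matrix genes TNC (12.3 to 5.91 FPKM) and fibronectin, FN1 (169 to 91.4 FPKM), fell. Epithelial junction genes were higher in 7 and lower in 9 of 20, with OVOL1 (2.53 to 9.36 FPKM) and CLDN4 (19.7 to 28.5 FPKM) higher and DSP (51.4 to 32.6 FPKM) and E-cadherin, CDH1 (69.1 to 48.2 FPKM), lower. Luminal urothelial markers were higher in 8 and lower in 3 of 15, with ELF3 (32.4 to 51.8 FPKM) and KRT18 (69.4 to 113 FPKM) higher and ERBB3 (6.72 to 4.06 FPKM) and ERBB2 (12.97 to 9.15 FPKM) lower. After length correction 5 luminal markers were higher and 5 lower, and the list median went from 0.22 to 0.03. Basal markers were higher in 8 and lower in 7 of 19, with KRT6A (302 to 424 FPKM) and TRIM29 (16.96 to 21.7 FPKM) higher and EGFR (187 to 93.8 FPKM) and COL17A1 (198 to 140 FPKM) lower. In sgNC the basal markers KRT5 and KRT14 were at 1195 and 707 FPKM, and the mesenchymal gene ZEB1 was at 0.046 FPKM. Whether such levels are those of T24 cells was not tested, and the identity of the line rests on the labels. Matrix protease and invasion genes were higher in 11 and lower in 4 of 19, with PLAUR (26.8 to 47.4 FPKM) and PLAU (104 to 149 FPKM) higher and ITGA2 (19.4 to 9.20 FPKM) and ADAMTS1 (21.2 to 14.1 FPKM) lower.

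Interferon-stimulated genes were higher in 9 and lower in 8 of 27, with IFITM1 (29.2 to 53.6 FPKM) and BST2 (208 to 310 FPKM) higher and SAMD9 (42.2 to 16.8 FPKM) and SAMD9L (6.97 to 4.09 FPKM) lower. Iron handling genes were higher in 10 and lower in 5 of 22, among them the ferritin light chain FTL (3055 to 4941 FPKM), VDAC2 (45.5 to 73.8 FPKM) and IREB2 (4.08 to 2.19 FPKM). G1/S genes were higher in 14 and lower in 7 of 31, with PCNA (129 to 189 FPKM) and RRM2 (10.6 to 17.004 FPKM) higher and E2F2 (4.18 to 2.42 FPKM) and POLE (6.80 to 4.48 FPKM) lower. Of 17 replication-dependent histone genes, 7 were higher, such as HIST1H1C (93.4 to 179 FPKM) and HIST1H4I (11.7 to 24.3 FPKM), and 4 lower, such as HIST1H2BO (4.88 to 2.72 FPKM) and HIST1H3B (2.02 to 1.19 FPKM). After length correction 5 histone genes were higher and 7 lower, with the list median going from 0.23 to -0.06, and 7 interferon-stimulated genes were higher and 9 lower, with a median going from 0.06 to -0.05. Cholesterol synthesis genes were higher in 13 and lower in 6 of 25, with INSIG1 (44.8 to 88.3 FPKM) and MSMO1 (66.5 to 121 FPKM) higher and SREBF2 (52.1 to 35.3 FPKM) and LSS (10.9998 to 6.58 FPKM) lower. Apoptosis regulators were higher in 15 and lower in 6 of 29, with MCL1 (95.4 to 149 FPKM) higher and FADD (7.40 to 3.23 FPKM) and XIAP (8.48 to 5.13 FPKM) lower. WNT targets were higher in 2 and lower in 3 of 10, with MYC (134 to 167 FPKM) and ASCL2 (0.578 to 1.11 FPKM) higher and ZNRF3 (3.13 to 1.98 FPKM) and CCND1 (42.2 to 37.5 FPKM) lower. The call of ASCL2, at a log2 fold change of 0.42, ended with all the length corrections, at 0.15 with the first (limma adjusted p = 0.244), and that of MYC, at 0.32, with the second (0.05, limma adjusted p = 0.26). Of 15 OTU family genes, which include OTUD1, 9 were higher, such as TNFAIP3 (53.3 to 74.8 FPKM) and OTUD6B (8.32 to 13.5 FPKM), and 3 lower, such as VCPIP1 (4.04 to 2.65 FPKM) and OTUD7B (3.29 to 2.37 FPKM). The call of OTUD7B, at -0.35, ended with length and GC correction (-0.15, limma adjusted p = 0.0525), and that of HIST1H3B with limma-voom (-0.71, adjusted p = 0.18). Adjusted over the list alone, counts in these 15 lists moved by at most 1 in either direction.

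Markers of other cell types were too few among the tested genes for a set test. Of the fibroblast markers COL1A1 (5.87 to 3.85 FPKM) and FAP (4.01 to 3.37 FPKM) were tested. The call of FAP, at a log2 fold change of -0.20, ended with length correction (-0.15, limma adjusted p = 0.0613). It also ended without a filter (-0.20) and without some replicates (-0.17 to -0.21). Of the endothelial markers 2 were tested, including CDH5 (2.20 to 0.644 FPKM), and of the leukocyte markers only CSF1R (1.14 to 0.429 FPKM). The highest level of any of these markers in any library was 6.17 FPKM.

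**Figure D4:**
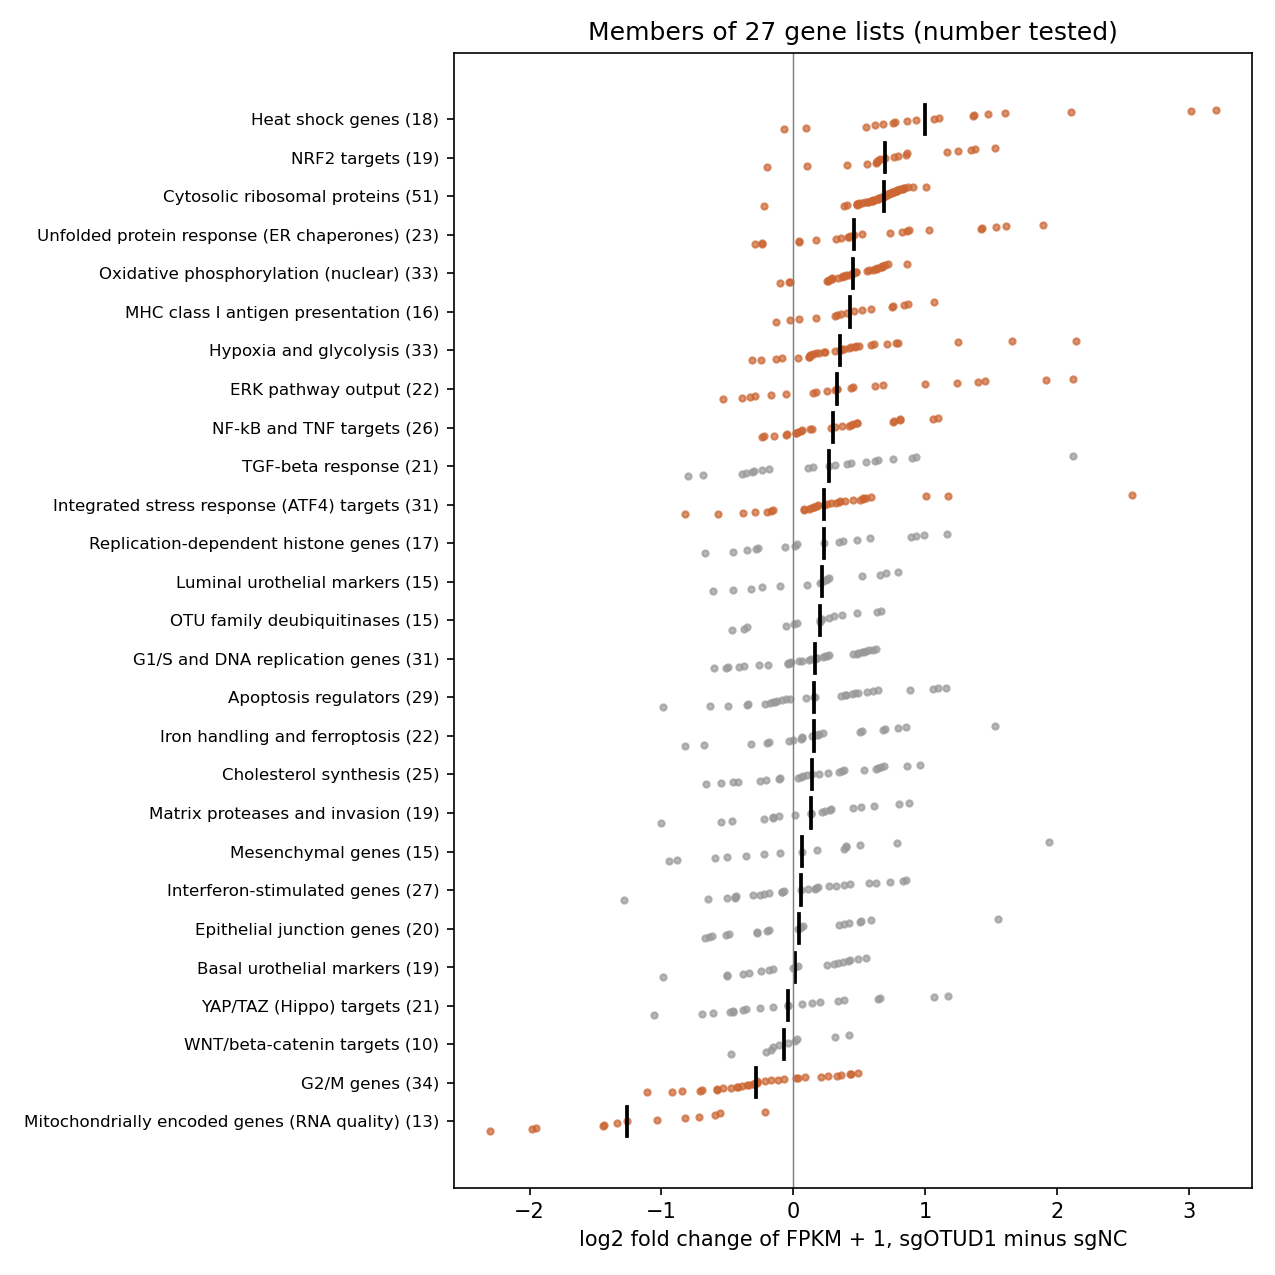
Log2 fold change on the FPKM + 1 scale (horizontal axis, sgOTUD1 minus sgNC) of each tested member of 27 gene lists, with the list median as a black bar and lists past camera at an adjusted p under 0.05 in orange. Heat shock genes have the highest median, 1.00, and the mitochondrially encoded mRNAs the lowest, -1.26.

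Fold change was related to gene length. Across 11372 nuclear protein-coding genes, Spearman's rho between log2 fold change and exon length was -0.38, a correlation across genes, which are not independent replicates. The median was 0.31 in the shortest of 10 equal bins of these genes and -0.22 in the longest. After length correction 3820 genes were higher and 4120 lower, and 12 of the 13 lists passed camera in the same direction. Exon length is the union of annotated exons and may exceed the length of the transcripts present. It was 8626 nt for RPL14 and 6079 nt for B2M. Their log2 fold changes went up with the correction, from 0.83 to 0.93 and from 1.07 to 1.09. The median of the ribosomal protein list went from 0.69 to 0.52. The lists that passed are thus not shown to be free of an effect of transcript length. Among the 9 other splits of the 6 libraries, camera passed up to 9 lists, although at most 1 gene was called. Each of those splits sets 2 libraries of a group and 1 of the other against the rest, so a part of the group difference remains in them.

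**Figure D5:**
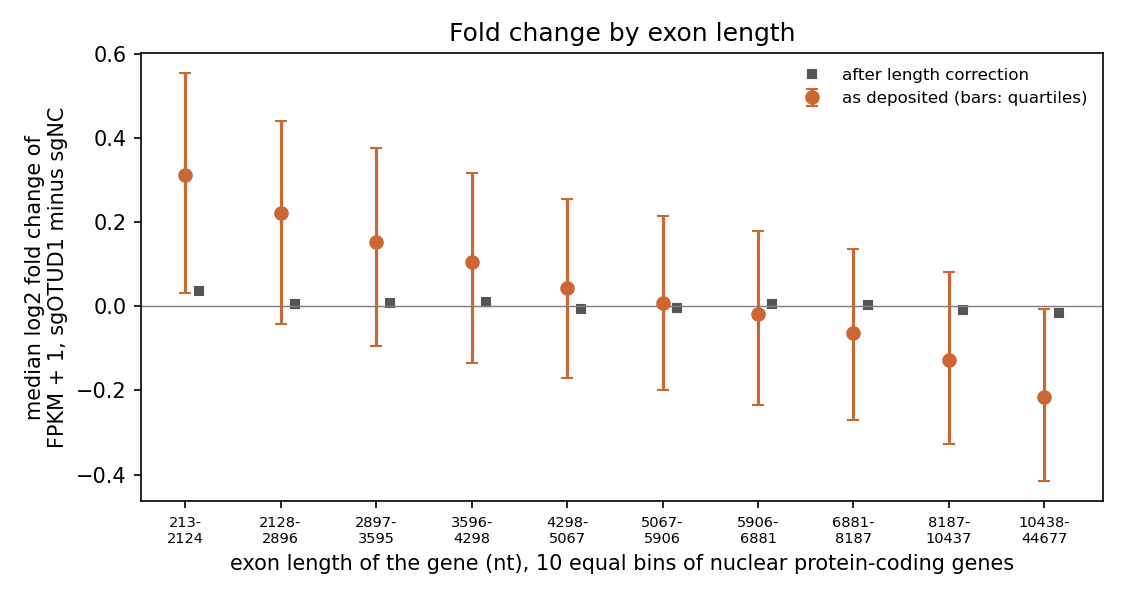
Median log2 fold change on the FPKM + 1 scale (vertical axis, sgOTUD1 minus sgNC; bars are quartiles) of nuclear protein-coding genes in 10 equal bins of exon length in nt (horizontal axis), as deposited in orange and after length correction in grey. Medians as deposited run from 0.31 in the shortest bin to -0.22 in the longest, and corrected medians lie between -0.01 and 0.04.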

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

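The length, GC and limma-voom settings were chosen after the data were seen, the others before. The log2 fold change of OTUD1, 0.20, was 0.071 with median-ratio rescaling, 0.061 with TPM, 0.025 with length correction, 0.016 with length and GC correction and -0.060 with the second length correction, and it ranged from 0.17 to 0.24 without each replicate. Its limma adjusted p ranged from 0.00433 to 0.803 over all settings. TPM divides by the FPKM sum, 267282 in sgNC and 297034 in the libraries labelled sgOTUD1, and so lowers the latter for every gene. The length corrections take out a trend whose median was 0.15 in the bin of 2897 to 3595 nt, which holds OTUD1 (2933 nt). UBE2C (1286 nt), at 0.44, was at 0.15 with the first length correction and -0.013 with the second. It lies in the shortest bin, with a median of 0.31 before correction. Why the 2 corrections differ for it was not tested. Among genes of mean FPKM of at least 5, 3463 were higher and 1757 lower, so 66.3% of the calls were higher against 55.9% in the main test, with a median log2 fold change of 0.14; the cause was not tested. The threshold of more than 2-fold left 294 higher and 127 lower. The second length correction gave 3153 genes higher and 4614 lower, and 110 genes called in the main test were called in the opposite direction, against 11 with the first. Limma-voom on recovered reads gave 4856 higher and 4019 lower. Without each replicate, 4074 to 4308 genes were higher and 3059 to 3314 lower, and 13 lists passed camera each time. An estimated correlation left 0 of the 13 lists, or 2 after length correction, and fry called 24. With the replicate block, 4431 genes were higher and 3360 lower and 12 lists passed. The pairing check gave same-number correlations of 0.0016, -0.051 and -0.0007, so no pairing of the libraries by number was seen. It cannot exclude that libraries of the same number were prepared together. For the genes given by the rule for named genes, other than OTUD1, 1933 values over these settings kept their direction and side of the threshold, 19 lost the call and 1 changed sign; for the lists, 463 were unchanged in this sense, 6 lost the call and 6 gained it. In simulated reads for this comparison, over 14658 genes without a length trend, 86% of genes changed 1.5-fold were recovered. Of those calls 3.75% were false. With a simulated trend of -0.15 per doubling of length, 93.9% were false without correction and 22.1% with length correction. These shares depend on how many genes were changed in the simulation and do not carry over to the data.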

Other observations

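In 8 gene families outside the fixed lists, all chosen after their values were seen, the counts only describe that choice, and the set tests run on them are no independent evidence and are left out. Of 36 proteasome subunit genes 30 were higher and 1 lower in the libraries labelled sgOTUD1, with a median log2 fold change of 0.33, and all 8 genes of the cytosolic chaperonin CCT, which folds actin and tubulin, were higher, with a median of 0.49. Of 78 mitochondrial ribosomal protein genes 57 were higher and 2 lower, with a median of 0.32. After length correction these 3 medians were 0.22, 0.36 and 0.12, and with TPM 0.21, 0.34 and 0.20. Of 187 sense-intronic genes 61 were higher and 11 lower, with a median of 0.15, and -0.12 after length correction. Of 107 snoRNA genes 19 were higher and 7 lower, with medians of 0.24 and -0.04. The correction was fitted on nuclear protein-coding genes alone and subtracted from every class of gene. These changes of sign thus come from a trend of protein-coding genes, and whether it holds in these classes was not tested. With TPM the medians of the sense-intronic and snoRNA genes were 0.13 and 0.25.

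Collagen genes were lower in 11 and higher in 0 of 16 members, with a median of -0.41, and -0.24 after length correction. Of 8 laminin genes 1 was higher and 5 lower, with medians of -0.21 and -0.17. Numbered ZNF zinc-finger genes were lower in 118 and higher in 37 of 301 members, with medians of -0.15 and -0.16. With TPM the medians of these 3 families were further from 0, at -0.63, -0.37 and -0.33. Of 8 immediate-early genes 6 were higher, NR4A2 (1.17 to 5.22 FPKM), ARC (0.851 to 3.60 FPKM), EGR2 (0.837 to 2.23 FPKM), NR4A1 (1.65 to 2.59 FPKM), FOS (42.9 to 54.3 FPKM) and IER2 (30.7 to 36.8 FPKM), FOSB (10.4 to 7.38 FPKM) was lower and EGR1 was at 26.9 and 25.9 FPKM. The libraries labelled sgOTUD1 listed 22511 ± 257 genes above 0, against 24114 ± 152 in sgNC (SD, n = 3 each).

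Tests written before their result was seen were those of lincRNA genes, of genes of mean FPKM of at least 20 and of chromosome windows; all the other tests of patterns here, including those on GC content, mean FPKM and pseudogenes, the mitochondrial transcripts, the stress genes and the splits, were chosen after.

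Longer genes were lower and shorter genes higher in the libraries labelled sgOTUD1, with slopes per doubling of exon length of 0.08 ± 0.018 in sgNC and -0.08 ± 0.015 in the libraries labelled sgOTUD1 (SD, n = 3 each, relative to the mean of all libraries). Compression by the offset is argued against by genes of mean FPKM of at least 20, where rho was -0.46, and GC content by a partial rho of -0.42 given GC. Fold change was also related to level, with a rho of 0.33 with mean FPKM, and the partial rho with length given mean FPKM was -0.33. Exon length, the union of annotated exons, only stands in for RNA length here. A loss of long RNA that acts on every class of transcript predicted a rho of -0.2 or lower in lincRNA genes, where rho was -0.016. Its interval over resampled genes, which does not measure the spread between libraries, was -0.11 to 0.07. It reaches past the bound of -0.1 set for excluding such a loss, which therefore cannot be told apart from a difference in mRNA regulation. Protein-coding genes drawn at the same levels had a median rho of -0.19, itself short of -0.2, so a trend that is present can miss that prediction. None of 1000 draws reached the lincRNA value. In 578 processed pseudogenes, which can take reads of their parent genes, rho was -0.08. The interval there, -0.16 to 0.0008, also reaches past the bound of -0.1. RNA handling at harvest, the OTUD1 guide itself and any other difference between the control and the sgOTUD1 cells follow the groups in this design, and all stay open. The labels do not say whether the cells of either group are a clone or a pool.

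The 13 mitochondrially encoded mRNAs were lower. The length trend is argued against by nuclear protein-coding genes of such lengths (up to 1812 nt, 757 genes). Their median was 0.33 and 5% of them lay under -0.46, against a median of -1.26 for the 13 mRNAs. With TPM the median of the 13 mRNAs was -1.42. TPM lowers the libraries labelled sgOTUD1 for every gene, so it could only move this median away from 0 and does not test scaling. A scaling factor moves all genes of a library nearly alike, and the median of all tested genes was 0.03. A uniform loss of mitochondrial RNA predicted a fall of the rRNA genes too, and these averaged 0.16 (MT-RNR1 0.46, MT-RNR2 -0.14). They went in opposite directions, and their levels can depend on how RNA was selected for the libraries, which was not examined. The rRNA genes thus argue against a uniform loss only as far as their reads follow their levels in the cells. The 13 mRNAs themselves ranged from -2.30 to -0.21. Of 22 tested tRNA genes 18 were lower and 0 higher, and MT-TA was listed at 0 in all libraries labelled sgOTUD1. Levels of tRNA genes in sgNC ran from 1.60 FPKM for MT-TF to 2871 FPKM for MT-TN, and MT-TA was at 6.53 FPKM. For such short genes a low FPKM rests on few reads. Whether the reads come from mature tRNA or from other RNA was not tested. A change in mitochondrial mRNAs and in reads on tRNA genes, apart from rRNA, is a hypothesis that may involve transcription, processing or decay, none of which these data separate. RNA quality, of which this list had been fixed as a sign, may follow the groups and stays open.

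Heat shock and ER chaperone genes were higher. For heat shock genes the length trend as the whole cause is argued against by a median of 0.81 after its removal (0.70 with the second correction). For ER chaperone genes that median was 0.35 (0.29 with the second correction), between the bounds of 0.2 and 0.4, so a part played by the length trend stays open although 19 of 23 were still higher. TPM lowers the libraries labelled sgOTUD1 for every gene, and with it the list medians were 0.88 and 0.33, against -0.10 for all tested genes. This argues against the deposited scaling as the whole cause, for that rescaling alone. An immediate-early response at harvest cannot be told apart from a lasting stress response, since the median of 8 such genes was 0.39, with 6 higher and 1 lower, between the bounds of 0.2 and 0.5, and stress of the cells before lysis may follow the groups.

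For a copy-number difference, no window of 41 neighbouring genes reached the median of 0.3 set beforehand. The largest was 0.26 after length correction (chromosome 8, 67422038 to 93731527, permutation p = 0.106, 1000 permutations). In the permutations 95% of the largest medians lay under 0.28. Windows of this size cannot show differences over fewer genes, and differences that shift expression by less than 0.3 are not excluded.

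Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called genes (8192, against at most 1) and only 1 as many lists past camera (13, against at most 9). The other splits mix the groups and keep a part of their difference. With 10 splits no share under 0.05 can be reached.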
